A study of Mus musculus with 12 samples.

How the data were processed

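RNA was sequenced from mouse embryonic stem cells (ESC) cultured in 2i medium, which holds inhibitors that keep the cells in a naive pluripotent state, and from neural progenitor cells (NPC) derived by differentiation. Each cell type was represented by wild-type (WT) cells, cells with 1 altered copy of Chd8 (HET) and cells with both copies altered (KO), with 2 libraries in each of the 6 groups and 12 libraries in all. CHD8 is a chromatin remodelling helicase. Per the labels' protocols, the libraries were stranded and made with a SMARTer kit from total RNA depleted of ribosomal RNA. Cutadapt 1.16 and kallisto, with the mouse build mm9, are named in the submitters' processing notes; the kallisto version is not given in the sources used here. The labels do not say whether libraries of a group came from separate cultures or separately derived lines, so the p-values measure the spread between these libraries, which may be technical. They also do not say how many lines carry each genotype.

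The deposited files give, per the file headers, an estimated count, a TPM value, a length and an effective length for each of 55419 transcripts per library. Estimated counts are expected counts, in which kallisto shares a read among the transcripts it is compatible with, so isoforms of a gene and near-identical paralogs can exchange reads and single transcripts are less certain than whole genes. The deposited TPM values are scaled within each library and were used for 1 alternative test only. The transcripts carry UCSC-style identifiers, and the files do not pair them with gene names. Of these identifiers, 0 matched the gene name tables used here. The sums per gene planned before the data were examined, the level of Chd8 in each library, which would have checked the genotype labels, the marker genes, the fixed gene lists and the removal of structural RNAs were therefore not run. Transcripts took the place of genes throughout, and a gene with several transcripts can be counted more than once. The rule for named genes was kept where it needs no symbol. It asked for an adjusted p under 0.05, a mean CPM (counts scaled to library size) of at least 5 in the compared libraries and no overlap between the groups, and of those left at most 2 transcripts with the largest rise and 2 with the largest fall are printed per comparison.

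In the deposited counts, 552 transcripts in 217 sets had values that could not be told apart in any library (equal to 2 decimals), and each set was merged, which left 55084 features. Counts were rounded to whole numbers. With edgeR 4.0.16 in R 4.3.3, transcripts were kept by filterByExpr (minimum count 10), scaled by TMM and fitted in 1 quasi-likelihood model over all 12 libraries with a mean per group (glmQLFit with robust moderation). In all, 30021 transcripts were tested two-sided with Benjamini-Hochberg adjustment in each comparison at a threshold of 0.05. The common dispersion was 0.35, which is a biological coefficient of variation of 0.592, with 6 residual degrees of freedom and a median of 2.15 prior degrees of freedom. The printed standard errors are the log2 fold change divided by the square root of the F statistic. Total estimated counts ran from 9062447 to 14766212 per library.

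On simulated counts with 200 transcripts changed per comparison among the 30021, edgeR recovered 2.0% of changes of 2-fold, 28.0% of 4-fold and 34.0% of 8-fold for KO against WT in ESC, with 0 false calls. For KO against WT in NPC it recovered 4.0%, 30.0% and 38.0%, with 2 false calls among 38. On the same counts DESeq2 1.42.0 made 98 false calls among 170 for KO against WT in ESC and 90 among 163 in NPC, and limma 3.58.1 made 9 among 42 and 16 among 63. In 20 simulations with no genotype effect, edgeR made at most 1 false call in any of the 6 genotype comparisons.

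Transcript sets were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Each set was defined in libraries that the tested comparison did not use, and the 24 set tests were adjusted together. A score per library was the mean log2 CPM (prior count 2) of the transcripts that edgeR called higher in KO than WT in the other cell type, minus the mean of those called lower. Its relation to the number of altered copies was tested by exact permutation over the 90 arrangements of 6 libraries, two-sided. The merging, the sets and the score were chosen after the data had been seen, the score after the principal components. So was a scan along the deposited row order, in which tested transcripts with a mean CPM of at least 2 were divided into 199 blocks of 100, and the median log2 fold change of each block was taken relative to the median block. A stretch was a run of at least 2 neighbouring blocks past 0.25 in the same direction. That limit was settled after other limits had been looked at, and 18 combinations of block size, CPM and limit were then compared. The files do not say what the row order follows. On simulated counts with 10 blocks lowered by 0.5 in KO, the scan found 10 of them in each cell type and 0 elsewhere.

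The alternatives planned before the data were examined were RLE size factors, no low-count filter, DESeq2, limma on log2(TPM + 1), the replicate number as a block, fits within a cell type and leaving out each library. Those added later were a minimum mean CPM of 10, the 2 most abundant transcripts left out, transcripts not merged, libraries thinned to the smallest total, the stretches left out, and a score from the 100 transcripts of lowest p in each direction.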

Results

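Transcript levels were measured in 12 libraries of mouse ESC and NPC that were WT, HET or KO for Chd8, to ask how the dose of this chromatin remodeller affects transcription in pluripotent cells and after differentiation towards the neural lineage. Total estimated counts rose with the number of altered copies in ESC, from 9062447 and 9840544 in the WT libraries to 14220515 and 14766212 in the KO libraries. In NPC the WT libraries were the deepest, at 12392099 and 13150215. A single transcript, uc009vew.1, held 10.1% to 27.4% of the counts of a library. The genotype labels were not checked against Chd8 itself, because the files do not pair transcripts with gene names.

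Cell type separated the libraries first. The first principal component of log2 CPM held 31.5% of the variance and parted all ESC libraries from all NPC libraries. The second held 10% and ordered WT, HET and KO libraries in both cell types without overlap. Replicates of a group correlated at r = 0.856 to 0.885 across transcripts, while libraries of different cell types correlated at 0.746 to 0.803. Genotypes of a cell type were as close as replicates in places. A library of another genotype reached r = 0.872 with a WT ESC library, where the replicates had 0.856, r = 0.886 with HET ESC and with KO ESC (replicates 0.884 and 0.885) and r = 0.869 with HET NPC (replicates 0.867). The WT ESC libraries were the least alike of any pair of replicates, at r = 0.856, and lay at -26.9 and -128.8 on the second component. Transcripts are not independent replicates, so these correlations describe the libraries only.

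**Figure D1:**
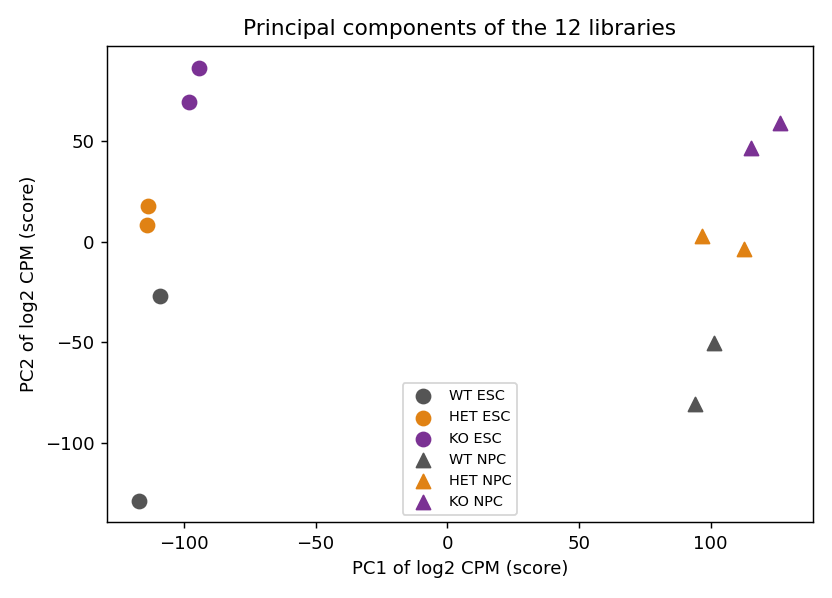
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, with circles for ESC, triangles for NPC and colours for genotype. The first component parts the cell types and the second orders WT, HET and KO in each, with WT ESC replicate 2 lowest at -128.8.

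Differentiation changed many transcripts in every genotype. In WT cells 2051 transcripts were higher and 1601 lower in NPC than in ESC (edgeR quasi-likelihood test, adjusted p under 0.05), in HET cells 1892 were higher and 1550 lower, and in KO cells 1979 were higher and 1926 lower. Other tools gave more calls. Limma also gave another balance, but it used TPM values with no further scaling between libraries, and whether that moved the balance was not tested. DESeq2 called 6571, 6674 and 6971 transcripts in WT, HET and KO, and limma called 6288, 5253 and 5612, of which 5410, 4320 and 4491 were higher in NPC. Of the edgeR calls, 1112 were higher in NPC in all 3 genotypes and 826 were lower, while 18 were called in opposite directions by a pair of genotypes. Independent lists would share 129 higher transcripts between WT and HET, where 1359 were shared. The fold changes of WT and HET correlated across transcripts at r = 0.386 and those of WT and KO at r = 0.357, with no library in common. The counts fell when a library was left out, in WT to 1802 without NPC replicate 1 and 1528 without NPC replicate 2, in HET to between 1553 and 2044 and in KO to between 1586 and 2122 for each of the libraries.

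In ESC, 215 transcripts were higher and 147 lower in KO than in WT (edgeR, adjusted p under 0.05, 362 in all). uc007ehl.2 rose from 0.155 ± 0.219 CPM in WT to 62.1 ± 4.15 in KO (SD, n = 2, edgeR adjusted p = 0.0258). uc012ami.1 had no counts in either WT library and 12.8 ± 4.63 CPM in KO (SD, n = 2, edgeR adjusted p = 0.0278). uc009npq.1 fell from 14.7 ± 0.839 to 1.11 ± 0.153 CPM (SD, n = 2), a log2 fold change of -3.72 (SE 0.515, edgeR adjusted p = 0.0299). uc008sso.1 had 10.2 ± 3.38 CPM in WT and no counts in KO (SD, n = 2, edgeR adjusted p = 0.0449). The number of calls was fragile. Of the 362, 131 had an adjusted p above 0.04 and 6 one under 0.01, and the edgeR count was 0 in a fit of the ESC libraries alone, where 3407 had an unadjusted p under 0.05. It was 4 without KO ESC replicate 2, 9 without KO ESC replicate 1, 74 without WT ESC replicate 2, 888 among transcripts of mean CPM at least 10, 214 without the low-count filter, 223 with limma and 2728 with DESeq2.

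HET ESC differed from WT ESC in 6 transcripts that were higher and 4 that were lower (edgeR, adjusted p under 0.05). uc009tkb.1 rose from 0.547 ± 0.103 to 23.2 ± 1.67 CPM (SD, n = 2), a log2 fold change of 5.37 (SE 0.301, edgeR adjusted p = 0.00263), and stood at 30.3 CPM in KO ESC. uc007pap.2 rose from 1.89 ± 0.832 to 19.7 ± 0.793 CPM (SD, n = 2, edgeR adjusted p = 0.0226). uc007urk.2 fell from 322 ± 42.8 to 106 ± 8.82 CPM (SD, n = 2, edgeR adjusted p = 0.0104), and uc008lju.2 from 30.3 ± 0.346 to 10.8 ± 0.23 CPM (SD, n = 2, edgeR adjusted p = 0.038). In KO ESC uc007urk.2 stood at 99.3 CPM, but uc008lju.2 stood at 26.6 CPM, close to WT. All 6 higher transcripts and 1 of the 4 lower ones were also called in KO ESC. Independent lists would share 0.043 of the higher ones, but these comparisons share the WT libraries, so part of the overlap may come from the shared controls. Simulations with no effect made 0 calls for HET ESC, so the 0 calls that they shared cannot measure that part. KO and HET ESC differed in 1 transcript, uc011zak.1, which had no counts in HET and 23.6 ± 1.40 CPM in KO (SD, n = 2, edgeR adjusted p = 0.033). It stood at 8.22 CPM in WT ESC, so HET did not lie between WT and KO. The HET count by edgeR was 0 in a fit of the ESC libraries alone, where 1977 had an unadjusted p under 0.05, and 1058 by DESeq2. It was 3 and 5 without HET ESC replicate 1 or 2, 30 without WT ESC replicate 1 and 49 without WT ESC replicate 2.

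In NPC, 23 transcripts were higher and 41 lower in KO than in WT (edgeR, adjusted p under 0.05). uc007ulo.1 rose from 0.982 ± 0.499 to 18.4 ± 6.93 CPM (SD, n = 2), a log2 fold change of 4.21 (SE 0.481, edgeR adjusted p = 0.0385). uc007pbc.2 rose from 3.26 ± 1.15 to 43.4 ± 3.03 CPM (SD, n = 2, edgeR adjusted p = 0.0417) and stood at 34.8 CPM in HET NPC. uc009uzd.1 fell from 58.8 ± 4.24 to 12.2 ± 0.010 CPM (SD, n = 2, edgeR adjusted p = 0.0145), and it was also lower in KO than in HET NPC (edgeR adjusted p = 0.0425). uc011wws.1 fell from 23.2 ± 3.51 to 4.18 ± 0.969 CPM (SD, n = 2, edgeR adjusted p = 0.042). HET NPC differed from WT NPC in 3 transcripts, all higher and all called in KO NPC too. All 3 lay inside the stretches of neighbouring rows described below. Among them was uc011ysu.1, which rose from 7.06 ± 1.58 to 49.7 ± 2.13 CPM (SD, n = 2, edgeR adjusted p = 0.0223). None was lower by edgeR, where 2372 transcripts in both directions had an unadjusted p under 0.05, and DESeq2 called 444 lower. The HET count was 0 without either WT NPC library, with 1839 and 1829 at an unadjusted p under 0.05, and 1 without HET NPC replicate 1. The KO count by edgeR was 0 in a fit of the NPC libraries alone, without WT NPC replicate 1 and without KO NPC replicate 1, where 4313, 2615 and 2486 had an unadjusted p under 0.05. It was 4 without KO NPC replicate 2, 7 without WT NPC replicate 2, 485 at a mean CPM of at least 10, 433 with limma and 2241 with DESeq2.

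The KO calls of the cell types, which share no library, overlapped in direction. Of the transcripts called higher in KO, 12 were called in both ESC and NPC, where independent lists would share 0.165, and of those called lower 11 were shared, where 0.201 would be. None of them was called in opposite directions. The 23 shared calls depended on single libraries. Their number was 15 without WT ESC replicate 1, 6 without WT ESC replicate 2, 1 without either KO ESC library or WT NPC replicate 2, 2 without KO NPC replicate 2, and 0 without WT NPC replicate 1 or KO NPC replicate 1. It was 1 in the fit without the stretches of neighbouring rows that moved together in the mutants, and 627 with DESeq2. Transcripts called higher in KO ESC had a median log2 fold change of 0.36 in KO NPC and 0.40 in HET NPC, with 80.0% and 78.1% of the 215 above 0 (camera, adjusted p = 3.73e-27 and 3.81e-30, both 0.00101 with an estimated correlation). Those called lower in KO ESC had a median of -0.55 in KO NPC and -0.17 in HET NPC (camera, adjusted p = 1.98e-29 and 3.69e-08, 0.000658 and 0.00472 with an estimated correlation). In the reverse test, transcripts called higher in KO NPC had a median of 0.875 in KO ESC and those called lower one of -0.459 (camera, adjusted p = 3.65e-43 and 4.1e-26, 0.000826 and 0.00317 with an estimated correlation). Part of each set lay in the stretches. Among the 105 higher transcripts outside the stretches the medians were 0.149 in KO NPC and 0.126 in HET NPC, with 66.7% and 58.1% above 0 (camera with an estimated correlation, adjusted p = 0.00766 and 0.0382). Among the 78 lower ones they were -0.349 and -0.159 (adjusted p = 0.00766 and 0.0382 in the same way). In the reverse test outside the stretches, the 12 transcripts higher in KO NPC had a median of 0.273 in KO ESC, with 58.3% above 0, and did not pass (adjusted p = 0.157 in the same way), while the 22 lower ones had a median of -0.371 (adjusted p = 0.0366). The interaction test called 1 transcript for KO, uc009tkb.1 (edgeR adjusted p = 0.0256), a call that ended without WT ESC replicate 1, KO ESC replicate 2 or any WT or KO NPC library (adjusted p = 0.0529 to 0.12). By count, edgeR called more KO transcripts in ESC than in NPC while limma called fewer.

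HET libraries lay between WT and KO. On the score built from the KO calls of NPC, HET ESC libraries stood 1.27 ± 0.101 above WT and KO ESC libraries 2.08 ± 0.035 (log2, SD, n = 2), so the HET shift was 61.2% of that of KO. Such a share is a mean over the calls and need not hold for each of them. On the score built from the KO calls of ESC, HET NPC libraries stood 0.64 ± 0.009 and KO NPC libraries 1.03 ± 0.051 above WT, and the share was 61.7%. Over 6 libraries the score followed the number of altered copies in ESC (r = 0.989, rho = 0.956) and in NPC (r = 0.988, rho = 0.956), with an exact permutation p of 0.0222 in each, the smallest the design allows. The size rested on which calls passed. Without WT ESC replicate 2, 14 higher and 11 lower calls defined the score in ESC, which put HET ESC at -0.03 against 0.90 for KO (exact permutation p = 0.1), and without KO ESC replicate 1 HET NPC stood at 2.02, level with KO NPC at 2.02 (exact permutation p = 0.0667). With the 100 transcripts of lowest p in each direction, which needs no threshold, HET stood at 57.5% of KO in ESC and 63.6% in NPC, and at 40.1% and 62.5% without WT ESC replicate 2.

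**Figure D2:**
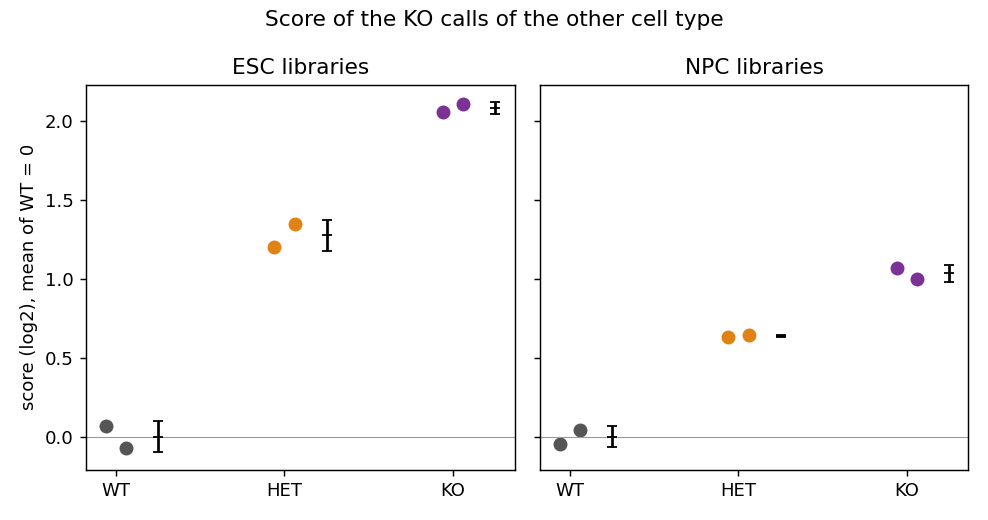
Score of each library (y axis, log2, WT mean set to 0) by genotype (x axis), in ESC from KO calls of NPC and in NPC from KO calls of ESC; points are libraries and bars the mean ± SD of 2. HET stands at 1.27 in ESC and 0.64 in NPC, between WT and KO in both panels.

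The fold changes of HET and KO against the same WT libraries correlated at r = 0.612 in ESC and r = 0.61 in NPC among the 10442 transcripts of mean CPM at least 10, where simulations with no effect gave means of 0.507 and 0.502. The covariance was 0.305 in ESC against a simulated 0.128, and 0.253 in NPC against 0.129. The simulations gave all groups the same dispersion. Spread of the shared WT libraries beyond it would also raise the covariance, so the excess alone does not show a shared effect. The WT replicates were the least alike in ESC (r = 0.856), though not in NPC (r = 0.885). Over all 30021 transcripts r was 0.556 in ESC, against 0.512, and 0.474 in NPC, below the simulated 0.486, while the covariances were 2.21 against 1.17 and 1.59 against 1.09.

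Transcripts that differentiation changes in the genotype left out of a comparison were tested as sets. Those higher in WT NPC than in WT ESC had a median log2 fold change of 0.15 in KO against HET ESC, with 63.3% of 2051 above 0 (camera, adjusted p = 0.00037, and adjusted p = 0.0443 with an estimated correlation). With an estimated correlation the adjusted p was 0.0382 for the members outside the stretches and 0.0509 in the fit without the stretches. In HET against WT ESC, transcripts higher in KO NPC than in KO ESC had a median of -0.09 (camera, adjusted p = 0.0119, and adjusted p = 0.25 with an estimated correlation) and those lower had a median of 0.10 (adjusted p = 0.00284, and adjusted p = 0.292 with an estimated correlation). Both calls ended without WT ESC replicate 1, at medians of -0.029 and 0.122 (adjusted p = 0.133 and 0.0605), and without HET ESC replicate 1, at -0.093 and 0.059 (adjusted p = 0.0819 and 0.0586). Among members outside the stretches the lower set fell to 0.061 and its call ended (adjusted p = 0.166), while it kept 0.094 in the fit without the stretches (adjusted p = 0.0245). In KO against WT NPC the medians were 0.10 for transcripts higher in HET NPC and -0.08 for those lower (adjusted p = 0.0272 and 0.0415, and 0.292 and 0.457 with an estimated correlation). These ended without WT NPC replicate 1, at 0.067 and -0.059 (adjusted p = 0.313 and 0.122), and without KO NPC replicate 1, at 0.063 and -0.031 (adjusted p = 0.113 and 0.519). The lower set also missed the threshold without WT ESC replicate 1 or HET ESC replicate 1 (adjusted p = 0.0549 and 0.0586), after thinning to the smallest library (0.0513) and among members outside the stretches (0.12), though not in the fit without the stretches (0.041). It stood at -0.177 without KO NPC replicate 2. In KO against HET ESC, transcripts lower in WT NPC had a median of -0.06 (adjusted p = 0.0201, and adjusted p = 0.292 with an estimated correlation), which became -0.017 without HET ESC replicate 1 and -0.062 without KO ESC replicate 1 (adjusted p = 0.182 and 0.0855). The adjusted p of this set was 0.12 among members outside the stretches and 0.035 in the fit without the stretches. Of the 12 differentiation sets, 1 held with an estimated correlation over all tested transcripts.

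Transcripts that neighbour each other in the deposited rows moved together in the mutants. The scan found 7 stretches, in 37 of 199 blocks, that held 18.3% of the tested transcripts. Over 18 settings of block size, CPM and limit the number of runs went from 2 to 11, and 59.5% to 100% of the stretches were found again. The longest, of 17 blocks, had a median log2 fold change of 0.37 in HET ESC, 0.43 in KO ESC, 0.34 in HET NPC and 0.16 in KO NPC. A stretch of 10 blocks stood at -0.55 in KO ESC and -0.50 in KO NPC, and at -0.08 and -0.07 in HET. Shifts also ran past the limits of the stretches. Every block from 148 to 156 lay above 0 in HET (0.066 to 0.247 in ESC, 0.145 to 0.32 in NPC). All of them lay below 0 in KO (-0.129 to -0.384 in ESC, -0.082 to -0.289 in NPC). Only blocks 150 and 151 counted as a stretch, so the others were treated as outside. The SD of block medians was 0.150 to 0.228 in the 4 comparisons of a mutant with WT, above the highest of 1000 shuffles of the row order in each, and 0.047 to 0.095 between replicates, where 0 blocks fell in a run. Of the 362 transcripts called in KO ESC, 179 lay inside the stretches, as did 30 of the 64 called in KO NPC and 17 of the 23 shared by both. So did 4 of the 10 called in HET ESC and all 3 called in HET NPC. Of the transcripts named above, uc007pap.2, uc007urk.2, uc007ulo.1, uc007pbc.2 and uc009npq.1 fall within the limits of stretches, by the order of their identifiers. They are thus not apart from the shifts of their neighbours. The stretches were chosen from these same comparisons, so an excess of calls inside them follows from the choice. With the stretches left out, edgeR called 16 transcripts in KO ESC, 5 in KO NPC, 2 in HET ESC and 0 in HET NPC, where 1689 had an unadjusted p under 0.05. The p-values of the first fit, adjusted over the transcripts outside the stretches alone, also gave 16 and 5. Of the 183 calls of KO ESC that lay outside the stretches, 16 thus passed when the transcripts inside were not adjusted with them.

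**Figure D3:**
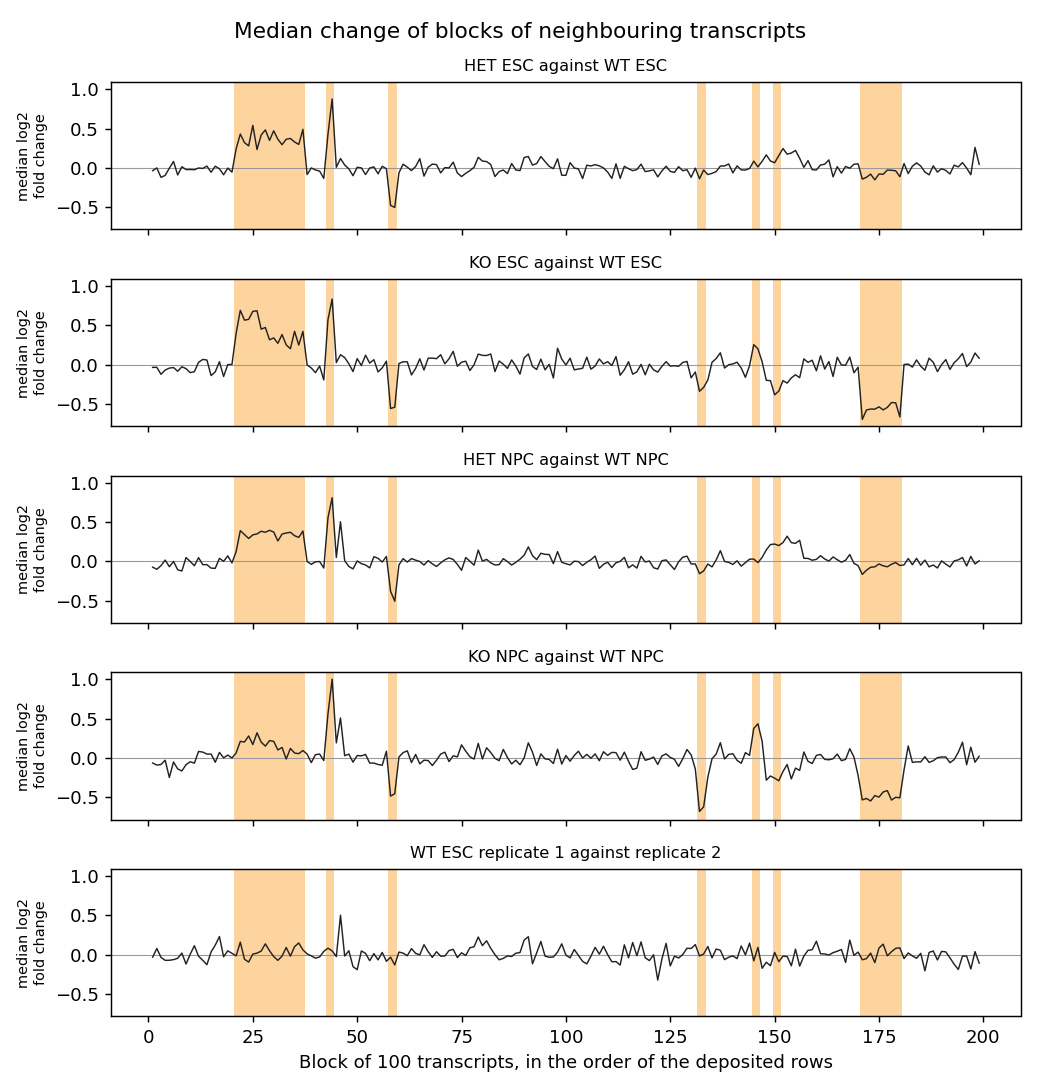
Median log2 fold change (y axis) of blocks of 100 transcripts in the order of the deposited rows (x axis), for the 4 comparisons of a mutant with WT and, at the bottom, for WT ESC replicate 1 against replicate 2; shading marks the 7 stretches. The stretch of 10 blocks stands at -0.55 in KO ESC and -0.50 in KO NPC, and the replicates show no run.

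Outside the stretches, the HET libraries also scored between WT and KO. The score from KO calls outside them was 0.44 ± 0.048 in HET ESC and 0.80 ± 0.029 in KO ESC, and 0.34 ± 0.016 in HET NPC and 0.71 ± 0.075 in KO NPC (log2, SD, n = 2, exact permutation p = 0.0222 in each). In HET ESC the 12 higher and 22 lower transcripts behind the score had medians of 0.055 and -0.133, with 58.3% and 45.5% above 0, and neither set passed with an estimated correlation (camera, adjusted p = 0.428 and 0.164). With the 13 higher and 3 lower calls of the fit without the stretches, the score was 0.762 ± 0.157 in HET NPC and 1.063 ± 0.041 in KO NPC (log2, SD, n = 2, exact permutation p = 0.0222). The covariance of HET and KO fold changes over the 8434 transcripts of mean CPM at least 10 outside the stretches was 0.289 in ESC and 0.209 in NPC, against simulated means of 0.130 and 0.122. These simulations also gave all groups the same dispersion, so spread of the shared WT libraries may add to the excess.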

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

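The tests by thinning and of the spread inside the stretch of 10 blocks were set before their results were seen, while the stretches themselves, the intervals of the ratios and the other tests of explanations in this part were chosen only afterwards.

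uc009tkb.1 differed between cell types in its response to both genotypes, by the interaction term of the edgeR model. Its HET effect in NPC minus that in ESC was -5.05 (log2, adjusted p = 0.0207) and the KO difference was -4.91 (adjusted p = 0.0256). It stood at 0.547 CPM in WT ESC, 23.2 in HET ESC and 30.3 in KO ESC, and at 83.3, 104 and 150 CPM in WT, HET and KO NPC. Leaving out a library gave differences of -4.85 to -5.33 for HET, which passed the threshold only without HET ESC replicate 2 or HET NPC replicate 2 (adjusted p = 0.0324 to 0.123 over the 8 libraries). For KO it gave -4.65 to -5.13, which passed only without WT ESC replicate 2 or KO ESC replicate 1 (adjusted p = 0.0261 to 0.12).

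The HET effect on differentiation transcripts also differed between cell types by camera. Transcripts higher in KO NPC than in KO ESC had a median difference of 0.102 (log2, adjusted p = 0.0317, and adjusted p = 0.292 with an estimated correlation), and those lower had -0.104 (adjusted p = 0.0474, and adjusted p = 0.483 with an estimated correlation). Without HET NPC replicate 2 the medians were 0.006 and -0.071 (adjusted p = 0.347 and 0.625). Both also missed the threshold without WT ESC replicate 1 (0.054 and -0.12), HET ESC replicate 1 (0.108 and -0.058) or WT NPC replicate 1 (0.061 and -0.096). The first missed it without HET ESC replicate 2 or either KO NPC library too, and the second without WT ESC replicate 2 or either KO ESC library (adjusted p = 0.0522 to 0.101 for these 6). Without HET NPC replicate 1 the second stood at -0.201.

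The stretches were chosen in single comparisons, which can favour a difference between cell types, so this was tested by camera in runs of blocks chosen by the mean shift of ESC and NPC, a choice that favours neither sign. In a run of 9 blocks inside the stretch of 17, the KO effect in NPC minus that in ESC was -0.291 (adjusted p = 3.65e-05, and adjusted p = 0.0211 with an estimated correlation). The runs of 2 blocks chosen in this way included a pair at -0.353 and 0.195 (adjusted p = 0.000212 and 0.0251, and adjusted p = 0.0976 and 0.111 with an estimated correlation). Leaving out a library gave -0.205 to -0.348 in the run of 9 blocks (adjusted p at most 0.00323). With an estimated correlation it missed the threshold there without WT ESC replicate 2, KO ESC replicate 1, WT NPC replicate 1 or any HET or KO NPC library (adjusted p = 0.0524 to 0.0779). The difference of -0.353 kept its call without any 1 library (adjusted p at most 0.012), at -0.256 to -0.53, the latter without KO ESC replicate 2. That of 0.195 missed it without either WT ESC library, KO ESC replicate 2, WT NPC replicate 1 or KO NPC replicate 2 (adjusted p = 0.0524 to 0.141), and ranged from 0.118 without WT NPC replicate 1 to 0.306 without WT ESC replicate 2.

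Neighbouring transcripts moved together in the mutants, and a difference in the copy number of genome segments between the lines is a candidate explanation, if the rows follow the genome, which the files do not say. A segment of changed copy number would shift most of its transcripts by a similar amount, so that their spread would be close to that elsewhere. In the stretch of 10 blocks the interquartile range of KO fold changes was at most 1.076 times that outside, as this would need. In the stretch of 2 blocks with medians above 0 in HET and below 0 in KO it was at most 1.091 times in the comparisons shifted by over 0.25, which also meets this need. The stretch of 17 blocks, at most 1.143 times there, and the pair of 2 blocks each whose KO shift differed by -0.353 and 0.195, at most 1.177 times, have such a spread too. But a segment carried by all ESC and all NPC of a genotype would be expected to shift both alike. The KO shift differed between them in all 3 at the preset correlation and in the first alone with an estimated one (camera, adjusted p = 0.0211, 0.0976 and 0.111). The labels do not say whether ESC and NPC share a line, nor what share of the cells would carry a segment. The difference thus cannot decide on copy number, and these 3 stay open. So do the remaining stretches of 2 blocks, at 1.242 to 1.685 times in the stretch with the widest spread, where HET ESC alone passed 1.5, and up to 1.351 times in the next. Bias between single libraries is argued against by 0 blocks in runs in the 6 replicate differences. After thinning, the stretch of 10 blocks kept a median of -0.557 in KO ESC. Thinning lowers all transcripts of a library alike, so this median was expected to stay and cannot decide on depth. Total counts rose with altered copies in ESC and fell in NPC (r = 0.955 and -0.787). The stretch stood below 0 in KO in both (-0.546 and -0.497), which argues against depth. A bias common to both libraries of a genotype, and a regional effect of the genotype itself, stay open, as the labels do not say how many lines were used.

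More transcripts were called for KO in ESC than in NPC by edgeR, though not by limma (223 and 433). After every library was thinned to the smallest total, the ratio was 4.75 (95% exact binomial interval 3.68 to 6.21, which treats calls as independent), so depth is argued against as the whole cause. Without the stretches the ratio was 3.2 (1.12 to 11.17), which leaves open that they account for it. The counts lie so close to the threshold that they do not themselves show a difference in effect between the cell types, which the interaction tests measure.

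HET libraries lay between WT and KO. In NPC the stretches are argued against as the whole cause, since the HET score from calls outside them was 0.338, beyond the spread of the WT libraries (SD 0.059), and both sets of these calls passed camera in HET NPC with an estimated correlation. With the calls of the fit without the stretches it was 0.762 (WT SD 0.105), where the 13 higher calls passed that test (adjusted p = 0.0292) and the 3 lower ones did not (adjusted p = 0.0509). In ESC this stays open, as the score was 0.44 (WT SD 0.135) but neither set passed that test. Regional shifts outside the defined stretches stay open as well. A single block there stood at 0.504 in HET NPC and 0.51 in KO NPC. The same block differed by 0.503 between the WT ESC replicates and 0.485 between the HET ESC replicates. In WT and HET NPC its replicates differed by -0.057 and -0.093, so it cannot decide on a regional effect of genotype. Depth is argued against by a correlation of -0.787 between total count and altered copies in NPC, against 0.955 in ESC, while the score rose in both. An effect of the dose of Chd8, the difference that the design names, stays open as untested, since its level could not be read from the files. HET did not lie between WT and KO in every shift. A stretch of 2 blocks stood at 0.143 and 0.211 in HET ESC and NPC but at -0.353 and -0.287 in KO. Blocks beside it moved the same way. The stretch of 17 blocks stood higher in HET NPC than in KO NPC (0.338 and 0.162). Elsewhere HET stood near KO, as in a stretch at 0.675 and 0.78 in ESC and 0.692 and 0.81 in NPC. In another these were -0.488 and -0.537, and -0.468 and -0.463. The remaining stretches lay nearer WT in HET, as the stretch of 10 blocks did (-0.08 and -0.067). The HET share of the score may average such unlike shifts, which was not tested. Differences between lines that HET and KO share for other reasons, such as a common origin, were not tested.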

How the results depend on the processing

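Chosen after the data were seen were the minimum mean CPM, the most abundant transcripts, merging, thinning, the stretches, and everything on transcript sets and scores. The planned removal of structural RNAs, the gene lists and the Chd8 level were not run, for want of gene names.

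The counts for NPC against ESC were within 1.5 times under RLE size factors, no low-count filter, the minimum CPM and the stretches left out. The genotype counts were not stable, and unless a cause is given it was not tested. In the order HET and KO against WT and KO against HET in ESC, then the same in NPC, the edgeR counts were 10, 362, 1, 3, 64 and 2. DESeq2 gave 1058, 2728, 1233, 957, 2241 and 729. It gave 6571, 6674 and 6971 for NPC against ESC in WT, HET and KO, and 264 and 1005 for the HET and KO interactions. It also gave 227 and 627 HET and KO calls in both cell types, against 2 and 23 by edgeR. On simulated counts, 53.6% to 59.2% of DESeq2 calls for a mutant against WT were false, at 81 to 98 among 142 to 170. That share depends on how many changes were simulated. It does not give the false share among the calls on the real counts, which was not measured. Limma on log2(TPM + 1) gave 15, 223, 3, 33, 433 and 6, 6288, 5253 and 5612 for NPC against ESC, of which 5410, 4320 and 4491 were higher in NPC, and 2 for the KO interaction. Mean CPM of at least 10 gave 29, 888, 50, 7, 485 and 1. Fits of a single cell type gave 0 in all 6 (edgeR), with 1977 to 4313 transcripts at an unadjusted p under 0.05; these have fewer residual degrees of freedom. With the stretches left out the counts were 2, 16, 1, 0, 5 and 2, and 0 HET and 1 KO calls were shared by the cell types. Part of the drop was the removal of calls inside, 179 in KO ESC, 30 in KO NPC and all 3 in HET NPC. Of the calls outside, the 183 in KO ESC fell to 16 and the 34 in KO NPC to 5. The p-values themselves barely moved, with a median ratio of 1.0 for KO ESC, so the adjustment over fewer small p-values accounts for that fall. No low-count filter gave 214 for KO ESC. HET NPC had 5 calls under RLE, under thinning and without the 2 most abundant transcripts; thinning also gave 2 for KO against HET ESC and 1 in NPC.

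The replicate numbers gave no sign of pairing across transcripts, as same-numbered deviations correlated at -0.051 to 0.062. A smaller shared part is not excluded. In a single block the replicates differed by 0.503 in WT ESC and 0.485 in HET ESC, though by 0.081 in KO ESC. With the replicate block the 6 genotype counts were 4, 53, 0, 0, 3 and 0, the interactions 0 and 0, and 0 HET and 2 KO calls were in both cell types. Of the 0 counts, HET NPC had 2236, KO against HET 2622 in ESC and 2079 in NPC, and the interactions 1409 and 2587 transcripts at an unadjusted p under 0.05.

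Leaving out each library in turn, where the lone library left is assumed to vary like the other groups, gave ranges of 3 to 49, 4 to 434, 0 to 4, 0 to 3, 0 to 7 and 0 to 1 for the 6 genotype counts, 1528 to 2592, 1553 to 2044 and 1586 to 2122 for NPC against ESC, and 0 to 6 and 0 to 30 for the HET and KO interactions. Calls in both cell types numbered 0 to 4 for HET and 0 to 15 for KO. The correlation of HET and KO effects ranged from 0.467 to 0.693 in ESC and 0.404 to 0.635 in NPC, where a mean CPM of at least 10 gave 0.61. The KO score ranged from 0.897 to 3.182 in ESC, where 5 of the 12 fits left enough calls to score, and 0.751 to 2.021 in NPC; its exact permutation p was 0.1 in ESC without WT ESC replicate 2, and in NPC 0.0667 without KO ESC replicate 1 or either HET NPC library, the last being the smallest that a lone HET library allows. With the 100 transcripts of lowest p per direction, HET lay between WT and KO in every fit that left out 1 library, at 40.1% to 71.3% of KO.

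Of the 12 differentiation sets 6 passed, 6 in the fit without the stretches, 5 after thinning, 4 for members outside the stretches, 1 with an estimated correlation, 1 with fry, 1 outside the stretches with an estimated correlation (adjusted p = 0.0382, though 0.0509 in the fit without the stretches) and 2 to 7 without a library. Of the 4 interaction sets 2 passed, 2 in the fit without the stretches (adjusted p = 0.041 for each), 1 after thinning, 0 for members outside the stretches (0.0523 and 0.0549), with an estimated correlation or with fry, and 0 to 2 without a library. Of the 8 sets of KO calls of the other cell type 8 passed, and 5 for members outside the stretches with an estimated correlation. In the fits that left out 1 library, every set kept the members called from all 12 libraries. Those fits therefore do not test how far the lists themselves depend on a library. In the fit without the stretches 6 of these had enough members, of which 5 passed, 4 with an estimated correlation. The named transcripts kept their direction in all 264 settings that gave a value, and 101 of these no longer passed the threshold. Across 18 block settings, runs held 11.5% to 23.6% of blocks; 2 settings with blocks of 50 and the lowest limit also gave 2 blocks in runs between replicates. Depth was not shown to limit the KO counts, as thinning every library to the smallest total gave 347 calls in ESC and 73 in NPC; more depth was not tested. On simulated counts of this design edgeR recovered 2.0% and 4.0% of changes of 2-fold for KO in ESC and NPC.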
